A study of Homo sapiens with 19 samples.

How the data were processed

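RNA was sequenced from 19 libraries of MDA-MB-231, an established human breast cancer line. The labels name TRI Reagent extraction of total RNA and the TruSeq RNA v2 kit, which does not mark the strand of origin. The submitters' processing notes name CASAVA 1.4, TopHat2, Partek and the hg19 genome without their roles or order, and the counting program and the version of DESeq2 are not given in the sources used here.

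Values came as 3 tables, each normalized separately by the authors. The deposited culture and siSCIRT tables hold log2-scale values made by DESeq2's variance-stabilizing transform, with a lowest value of 13.4 in every culture library and of 7.48 in every siSCIRT library. The deposited siEZH2 table holds normalized counts as signal on the linear scale, which are reads per gene divided by 1 size factor per library. The design assumed linear normalized values throughout. Because the transform has an exact inverse, the log2 values of both tables were turned back into normalized counts before any test. Dividing each library by its step between values then gave whole reads, and 100% of the values came out whole in each of the 19 libraries, at a tolerance of 0.05 reads. The recovered reads gave the depth of each library and served edgeR and DESeq2 as alternatives. Genes listed numbered 19021 for culture, 26955 for siSCIRT and 28870 for siEZH2. Gene identifiers and symbols are those of the tables, and coordinates were not used here because the annotation at hand belongs to another genome build. The exception is the list of genes that overlap SCIRT on the other strand, which came from that annotation.

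Library totals of recovered reads ran from 6104222 to 14781941 in the culture table, from 27989577 to 38955312 in the siEZH2 table and from 38635418 to 62218847 in the siSCIRT table. A count of 0 was read as up to 3 reads per library. Folds against a group with 0 reads are lower bounds against that floor, and folds against a group with 1 to 3 reads carry a 95% interval (exact Poisson, on the reads of the lower group). Such floors and intervals cover Poisson counting error only. The scatter between culture libraries was 1.84 to 1.96 times that error even for the weakest genes compared, so the intervals are too narrow.

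Groups came from the sample titles: adherent cells, 16 h spheres and 5 d spheres (n = 2 each), siSCIRT 1, siSCIRT 2 and their siNC controls (n = 3 each), and siEZH2 and its siNC controls (n = 2 each). In the siSCIRT table only the columns of siSCIRT 2 carry the siRNA's number, and the remaining siRNA columns were taken as siSCIRT 1 by inference. Each table was fitted on its own with limma 3.58.1 in R 4.3.3, as log2 of the normalized count plus 1, with eBayes (trend and robust), over genes with a mean of at least 10. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. There were 8 comparisons: 3 among the culture groups, each siSCIRT and their mean against siNC, siSCIRT 1 against siSCIRT 2, and siEZH2 against siNC. The p-values measure only the spread between these libraries, since the labels do not say whether replicates were separate cultures. Replicate numbers were not used to pair libraries. Differences between the siEZH2 and siSCIRT responses were tested in 1 limma fit over the 13 libraries of both siRNA tables, each response against the controls of its own table.

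A total of 26 gene lists, from RNAi targets and PRC2 subunits to cell cycle, lipid, hypoxia, matrix, inflammatory, cell type and RNA quality lists, were tested where at least 5 members passed the filter. The test was camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and camera with an estimated correlation and fry stood beside it. The directional p of fry asks whether a list moves 1 way on balance, its mixed p whether members change in either direction, and neither compares a list with other genes. Genes named in the text were the 10 largest rises and falls of each main comparison and the 5 largest of the others. These had a mean of at least 100 in the higher group, an adjusted p under 0.05, no overlap between groups and a proper gene symbol. For the siSCIRT mean, each siRNA had to pass alone as well. Up to 4 members per list with the smallest adjusted p, the RNAi targets and members needed to describe a list were added. The tests, lists, named-gene rule and alternatives were fixed before the data were examined, except the fit of the difference between the siRNA responses, the tests of starting level, scaling between libraries and abundant genes, and the alternatives named as added.

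Alternatives were a pseudocount of 8, no filter, a mean of at least 50, quantile normalization, eBayes without trend, the replicate number as a block, only the compared groups in the fit, edgeR 4.0.16 (quasi-likelihood, TMM), DESeq2 1.42.0, each library left out in turn, adjusted p under 0.01 for overlaps and the 200 largest changes for gene sets. The transformed values as deposited and counts of genes changed at least 2-fold were added after the data were seen. On the recovered reads edgeR called 7768, 7874 and 6585 genes in the culture comparisons (16 h and 5 d against adherent, 5 d against 16 h). It called 1704, 1576 and 2416 for siSCIRT 1, siSCIRT 2 and their mean, 0 for siSCIRT 1 against siSCIRT 2 and 1081 for siEZH2.

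The fits were tested on simulated data, negative binomial reads with the means, size factors and dispersions of the tables, in which 200 genes per comparison were changed. Of the genes changed 2-fold, limma found 82.0%, 82.0% and 80.0% in the culture comparisons, 84.0%, 78.0% and 84.0% for siSCIRT 1, siSCIRT 2 and their mean, 72.0% between the siSCIRTs and 74.0% for siEZH2. It called between 4 and 17 unchanged genes per comparison and 0 of the changed genes in the wrong direction. The genes were simulated independently of each other, with dispersions from these same libraries. A spread between cultures that the libraries do not hold was thus not simulated. Effects shared by libraries of the same replicate number were not simulated either. The shares found hold for that setting only.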

Results

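The data are RNA-seq values of MDA-MB-231, a triple-negative breast cancer cell line with mesenchymal features, from 19 libraries in 8 groups. Adherent cells grew in DMEM with fetal calf serum (n = 2), and spheres floated in DMEM/F12 with B27, EGF and FGF for 16 h (n = 2) or 5 d (n = 2). A further 13 libraries, titled spheres as well, came from cells transfected with siRNA and kept for 48 h in the sphere medium. These were siSCIRT 1, siSCIRT 2 and a control siRNA, siNC (n = 3 each), and siEZH2 with its own siNC (n = 2 each). The culture libraries held 6104222 to 14781941 reads, the siSCIRT libraries 38635418 to 62218847 and the siEZH2 libraries 27989577 to 38955312. The culture comparisons ask how the line's RNA differs between adherent cells and spheres, and between the sphere times. Adherent cells and spheres differ in medium, serum and added growth factors as well as in attachment. Effects of these on the sphere results below cannot be told apart. The siRNA comparisons ask what differs when a gene studied for its part in sphere formation is silenced. Counts of list members below are over all genes tested, and counts adjusted over the list alone were equal to them unless both are given. Errors of log2 fold changes are standard errors of the limma fit.

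SCIRT, a long noncoding RNA of the antisense class (RP5-1120P11.1 in the tables), stood at 3.77 and 3.04 normalized counts in the adherent libraries. It reached 45.8 and 29.3 in 16 h spheres and 62.1 and 73.9 in 5 d spheres. Against adherent cells it rose by 3.10 ± 0.41 on the log2 scale at 16 h (adjusted p = 4.2e-08) and by 3.97 ± 0.41 at 5 d (adjusted p = 1.8e-10). In its own knockdown, SCIRT held 264, 287 and 256 normalized counts with siNC, 121, 112 and 127 with siSCIRT 1 and 159, 105 and 117 with siSCIRT 2. The log2 fold changes were -1.16 ± 0.16 (adjusted p = 0.00032) and -1.10 ± 0.16 (adjusted p = 0.00066). EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2), held 518 and 529 normalized counts with siNC and 275 and 278 with siEZH2, a log2 fold change of -0.92 ± 0.15 (adjusted p = 6.3e-08). SCIRT in the siEZH2 table was at 144 and 196 with siNC and 143 and 118 with siEZH2 (-0.37 ± 0.18, adjusted p = 0.24).

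EZH2 also fell in the SCIRT knockdowns, from 2601, 2280 and 2699 normalized counts with siNC to 1670, 1741 and 1841 with siSCIRT 1 and 1842, 1847 and 1668 with siSCIRT 2. The log2 fold changes were -0.53 ± 0.08 (adjusted p = 0.00056) and -0.50 ± 0.08 (adjusted p = 0.001). In the culture series EZH2 fell from 518 and 490 normalized counts in adherent cells to 162 and 161 in 16 h spheres (-1.63 ± 0.12, adjusted p = 5.2e-15). It stood at 350 and 317 in 5 d spheres, below adherent cells (-0.59 ± 0.12, adjusted p = 3.8e-05) and above 16 h spheres (1.04 ± 0.12, adjusted p = 1.4e-09). The SCIRT values are uncertain in what they count, because the kit does not mark the strand and 2 genes overlap SCIRT on the other strand. The larger of these, C6orf223, was at 2.57 ± 2.77 in adherent cells, 2.98 ± 2.70 in 16 h spheres and 4.90 ± 0.392 in 5 d spheres (SD, n = 2 each), far below SCIRT in the spheres. In the knockdown it was at 74.1 ± 15.1 with siNC, 34.7 ± 5.86 with siSCIRT 1 and 48.3 ± 3.42 with siSCIRT 2 (SD, n = 3 each), with log2 fold changes of -1.07 (adjusted p = 0.00891) and -0.59 (adjusted p = 0.138).

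**Figure D1:**
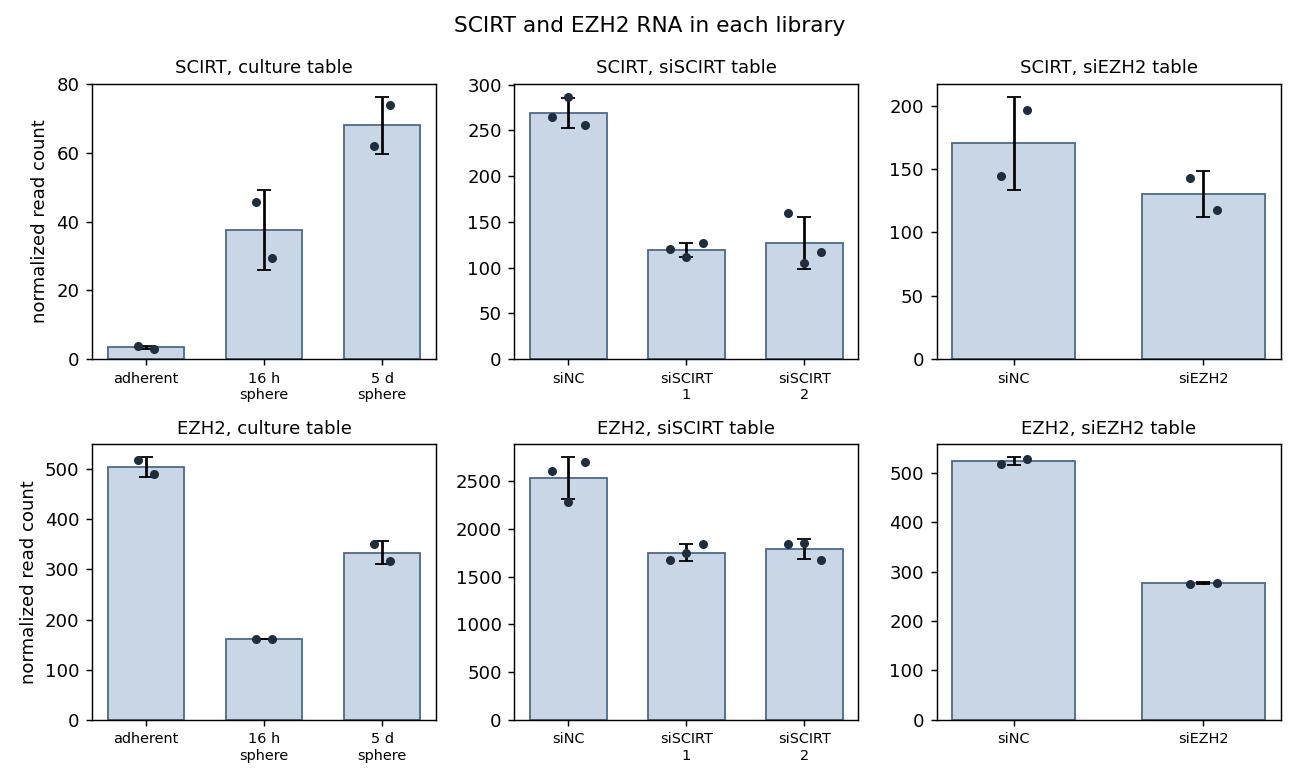
Normalized counts of SCIRT and EZH2 in each library by group, with points for libraries bars for group means and error bars for the SD; each table was normalized on its own. In the SCIRT knockdown the siNC libraries sit at 256 to 287 SCIRT counts and the siSCIRT libraries at 105 to 159.

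At 16 h the spheres held large amounts of RNAs that adherent cells hardly had. ANGPTL4, an inhibitor of lipoprotein lipase induced by hypoxia, rose from 8.04 ± 0.691 to 5666 ± 231 normalized counts (SD, n = 2 each), a log2 fold change of 9.29 ± 0.10. The lipoxygenase ALOX15B, at 0 reads in adherent cells, was at least 1209-fold higher at 2473 ± 66.6. SAA1, a serum amyloid, rose by 7.49 ± 0.15, CSF3, a granulocyte growth factor, by 7.40 ± 0.32, and the protease inhibitor SERPINA1 by 7.36 ± 0.38. The value of SAA1 is uncertain, since its reads are hard to tell from those of SAA2, which stood at 814 times the adherent level (interval 146 to 32141). LBP, a lipopolysaccharide-binding protein, stood at 849 times (290 to 4116), and CHI3L2, a chitinase-like protein, was at least 78.7-fold higher. Among the falls were ALPP, the placental alkaline phosphatase (1122 ± 12.9 to 11.4 ± 0.518 normalized counts, log2 -6.51 ± 0.19), and KISS1, a metastasis suppressor peptide (-6.41 ± 0.29). RELN, a secreted glycoprotein (-5.74 ± 0.43), and SLAMF7, an immune cell receptor (-5.46 ± 0.13), fell too. PSG5, PSG4 and PSG9, pregnancy glycoproteins whose near-identical sequences make each value uncertain, had log2 fold changes of -6.64 ± 0.38, -5.59 ± 0.38 and -5.43 ± 0.33.

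All 27 tested hypoxia and glycolysis genes rose at 16 h, 24 of them at least 2-fold (median log2 1.81, camera adjusted p = 1.87e-30). LDHA, which makes lactate, rose by 2.54 ± 0.01, the stress gene NDRG1 by 2.92 ± 0.02 and the collagen cross-linker LOX by 4.29 ± 0.03. Of 29 matrix and adhesion genes 22 rose and 4 fell (median 0.78, adjusted p = 7.63e-10), with fibronectin, FN1, up by 5.19 ± 0.02, its receptor chain ITGA5 by 3.74 ± 0.03 and the collagen COL6A3 by 5.61 ± 0.10. Mesenchymal genes gave 12 rises and 3 falls of 16 (median 1.26, adjusted p = 2.51e-08), among them the filament protein VIM at 0.95 ± 0.01. NF-kappaB and cytokine genes gave 15 rises and 3 falls of 22 (median 1.48, adjusted p = 3.17e-06), with the apoptosis inhibitor BIRC3 up by 3.71 ± 0.08 and NFKBIA, the NF-kappaB inhibitor, by 1.60 ± 0.05. Of 12 steroid, retinoid and aryl hydrocarbon genes 8 rose and 2 fell (median 2.37, adjusted p = 8.71e-06). The risers included the glucocorticoid targets FKBP5 (5.00 ± 0.04), TSC22D3 (4.69 ± 0.06) and PER1 (4.16 ± 0.12), while CYP1A1, the classic aryl hydrocarbon target, fell by 3.83.

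Cell cycle genes moved the other way at 16 h. Of 27 replication and E2F genes 26 fell, 22 at least 2-fold (median -1.86, adjusted p = 1.44e-15), such as CDC6, which loads the replicative helicase (-3.07 ± 0.11), the helicase subunit MCM3 (-1.58 ± 0.06) and the thymidylate synthase TYMS (-2.02 ± 0.09). In the mitosis list 22 of 25 genes fell (median -0.95, adjusted p = 3.99e-09), including its transcription factor FOXM1 (-1.57 ± 0.10) and the checkpoint kinase BUB1 (-1.77 ± 0.12), and the phosphatase CDC25B alone rose (0.25). Of 20 cholesterol genes 19 fell, or 20 adjusted over the list alone (median -0.83, adjusted p = 1.23e-13). HMGCS1, an early enzyme of the pathway, was at -1.57 ± 0.06 and the synthase FDPS at -1.43 ± 0.04. Fatty acid synthesis gave 10 falls and 1 rise of 14 (median -0.51, adjusted p = 9e-05, but adjusted p = 0.051 with an estimated correlation), with FASN, the fatty acid synthase, at -0.93 ± 0.03. YAP and TAZ targets gave 10 falls, 11 adjusted over the list alone, and 5 rises of 19 (median -0.59, adjusted p = 0.00251, but adjusted p = 0.0827 with an estimated correlation), with the matrix protein CYR61 at -2.05 ± 0.04 and the receptor kinase AXL at -1.59 ± 0.03.

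All 43 cytosolic ribosomal protein genes rose at 16 h (median 0.51, adjusted p = 8.22e-29), RPLP0 by 0.64 ± 0.02, although with quantile normalization their median was 0.06 and the adjusted p 0.0536. Mitochondrial transcripts, read as a sign of RNA quality, gave 12 rises and 1 fall of 13 (median 0.30, adjusted p = 9.69e-09, but adjusted p = 0.197 with an estimated correlation), and quantile normalization turned that median to -0.45. The 8 replication-dependent histones tested all rose, HIST1H2AC by 1.63 ± 0.09 (median 1.85, adjusted p = 1.2e-05, but adjusted p = 0.051 with an estimated correlation). Mitochondrial reads made up 6.83% to 6.89% of adherent libraries and 8.55% to 8.56% of 16 h spheres, and ribosomal RNA genes 0.72% and 2.03% to 2.04%. The ribosomal RNA genes include the mitochondrial ones, so the 2 shares overlap. Leaving out both sets removed about as many reads as the mitochondrial share alone, so nearly all ribosomal RNA reads were mitochondrial. Replication-dependent histone mRNAs mostly lack poly(A) tails, and their list was read as a sign of RNA quality too. Whether RNA quality moved this list was not tested. The unfolded protein and amino acid list gave 12 falls and 6 rises of 21 (median -0.38, adjusted p = 0.00992, but adjusted p = 0.12 with an estimated correlation), with CHAC1, a glutathione-degrading enzyme, at -2.71 ± 0.09 and the chaperone HSPA5 up by 0.58 ± 0.02. ERK feedback and immediate early genes gave 14 rises, 15 adjusted over the list alone, and 6 falls of 26 (median 0.39, adjusted p = 0.00835, but adjusted p = 0.13 with an estimated correlation and 0.145 with quantile normalization). AREG, an EGF receptor ligand, rose by 4.76 ± 0.16 and the ERK phosphatase DUSP6 by 1.61 ± 0.03.

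PRC2-repressed genes known from breast cancer lines gave 8 falls and 4 rises of 18 at 16 h, or 5 rises adjusted over the list alone (median -0.43, adjusted p = 0.0365, but adjusted p = 0.146 with an estimated correlation and 0.0672 with quantile normalization). The metalloproteinase inhibitors TIMP3 (-2.77 ± 0.03) and TIMP2 (-1.22 ± 0.03) and the WNT antagonist DKK1 (-1.87 ± 0.05) fell, and IGFBP3, an IGF-binding protein, rose by 3.03 ± 0.07. Of 9 luminal markers 6 rose and 2 fell (median 0.45, adjusted p = 0.0219, but adjusted p = 0.139 with an estimated correlation), among them the keratin KRT19 (0.77 ± 0.03) and the carbonic anhydrase CA12 (2.42 ± 0.11). The remaining lists did not pass camera. PRC2 subunits (4 up, 4 down of 10) included falls of PHF19 (-1.29 ± 0.11) and RBBP7 (-0.78 ± 0.06). Epithelial genes (6 up, 7 down of 14) included a rise of the mucin MUC1 (3.41 ± 0.16) and a fall of the junction protein OCLN (-2.86 ± 0.22), with a median of -0.25 against an upward test (adjusted p = 0.927). Stemness markers (6 up, 3 down of 11) had a median of 0.29 and a mean of -0.62, with the drug transporter ABCG2 at -4.58 ± 0.35 and CD44 at 0.30 ± 0.03, which quantile normalization turned to -0.04. Counts were 10 up and 9 down of 27 interferon-stimulated genes (median 0.10, test downward, adjusted p = 0.937), 4 up and 5 down of 16 p53 targets and 7 up and 10 down of 23 autophagy genes (median -0.05, mean 0.02). NOTCH and WNT genes (5 up, 2 down of 11) included rises of the ligand JAG1 (1.75 ± 0.06) and its target HES1 (1.85 ± 0.23). Of 6 blood and stromal markers 3 rose and 1 fell (adjusted p = 0.25), the collagen COL1A1 rising by 2.17 ± 0.34 and the proteoglycan DCN, at 1 read in adherent cells, standing at 2987 times their level (536 to 117962).

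In all, 7430 of 13789 genes were called at 16 h, 3775 higher and 3655 lower, and 1177 and 1186 of them at least 2-fold. The scatter between the libraries of a culture pair was 1.84 to 4.54 times that of counting alone from the weakest to the strongest genes, against 17.3 to 126 for the strongest genes of the siSCIRT table. From 20 to 10000 reads the culture scatter stayed at 1.84 to 2.15 times, while in the siSCIRT table it grew from 2.16 to 3.05 for the weakest genes. A spread between cultures would grow with reads against counting noise, so the culture pairs held little of it. Their SDs and p-values thus hold little spread between cultures. It is not known whether the libraries of a pair came from separate cultures, and if they were repeats of 1 culture, there is no such spread in them.

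By 5 d the spheres still held much more ANGPTL4 (log2 7.43 ± 0.10, at 1554 ± 66.1 normalized counts) and ALOX15B (at least 243-fold) than adherent cells. TXNIP, the thioredoxin-binding regulator of glucose uptake, rose from 83.3 ± 3.61 to 3612 ± 20.7 (SD, n = 2 each; 5.42 ± 0.06). The membrane protein PROM2 (5.50 ± 0.35), the oxidase NOX5 (5.22 ± 0.13) and the mucin MUC5B (5.19 ± 0.20) rose too. So did noncoding RNAs of RNA polymerase III, RN7SK (5.22 ± 0.11) and RN7SL1 (5.08 ± 0.19), which lack poly(A) tails and whose many genomic copies make their values uncertain, and RMRP stood at 114 times the adherent level (39.0 to 553). TNFSF15, a TNF family cytokine, fell (-5.02 ± 0.28) from 466 ± 8.16 normalized counts in adherent cells, as did RELN (-4.72 ± 0.43).

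The hypoxia list kept 23 rises, with 2 falls, of 27 genes at 5 d (median 1.03, adjusted p = 3.77e-15), with LDHA at 1.38 ± 0.01 and the mTOR regulator DDIT4 at 2.19 ± 0.03. Replication genes gave 22 falls of 27 (median -1.18, adjusted p = 5.51e-09), for example MCM2 (-1.69 ± 0.12). Mitosis genes gave 22 falls, 23 adjusted over the list alone, and 1 rise of 25 (median -0.83, adjusted p = 2.52e-08, but adjusted p = 0.058 with an estimated correlation), with the anaphase activator CDC20 at -1.38 ± 0.10 and the proliferation marker MKI67 up by 0.21. Fatty acid synthesis rose in 11 of 14 genes with 0 falls (median 0.54, adjusted p = 1.26e-05, but adjusted p = 0.058 with an estimated correlation), among them the desaturase SCD (0.62 ± 0.02) and the acyl-CoA synthetase ACSL3 (1.14 ± 0.04). Cholesterol genes gave 11 rises, 12 adjusted over the list alone, and 6 falls of 20 (median 0.20, adjusted p = 0.215). In the unfolded protein and amino acid list 19 of 21 genes fell and 1 rose (median -0.71, adjusted p = 1.42e-09), with the stress regulator NUPR1 at -2.31 ± 0.11. Matrix genes gave 22 rises and 4 falls of 29 (median 0.62, adjusted p = 7.11e-11), FN1 rising by 3.11 ± 0.02.

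Ribosomal protein genes gave 32 falls and 4 rises of 43 at 5 d, or 5 rises adjusted over the list alone (median -0.31, adjusted p = 5.19e-13, but adjusted p = 0.058 with an estimated correlation), with RPLP0 at -0.54 ± 0.02. Further lists passed camera at 5 d but not with an estimated correlation. These were mesenchymal genes (10 up, 5 down of 16, median 0.59, adjusted p = 0.00642, adjusted p = 0.119 with an estimated correlation and 0.0638 with quantile normalization) and YAP and TAZ targets (3 up, 12 down of 19, median -0.51, adjusted p = 0.000103, adjusted p = 0.0647 with an estimated correlation). PRC2-repressed genes (3 up, 11 down of 18, median -0.63, adjusted p = 0.0145) had an adjusted p of 0.131 with an estimated correlation, and steroid and related genes (7 up, 2 down of 12, median 0.92, adjusted p = 0.000259) one of 0.0733. Autophagy and lysosome genes (3 up, 13 down of 23, 14 adjusted over the list alone, median -0.27, adjusted p = 0.0013, adjusted p = 0.119 with an estimated correlation) included the receptor SQSTM1 at -1.03 ± 0.03. Luminal markers (4 up, 1 down of 9, median 0.81, adjusted p = 0.0158, adjusted p = 0.139 with an estimated correlation) included AGR2, a secretory pathway protein, at 1.32 ± 0.09. Histones, a sign of RNA quality, gave 7 rises of 8, with 1 fall adjusted over the list alone (median 0.88, adjusted p = 0.0198, adjusted p = 0.162 with an estimated correlation). Mitochondrial transcripts gave 11 rises and 2 falls of 13 (median 0.43, adjusted p = 4.6e-10, adjusted p = 0.186 with an estimated correlation), and their median was 0 with quantile normalization. The share of mitochondrial reads was 9.65% to 9.74% and that of ribosomal RNA genes, nearly all of it mitochondrial too, 2.22% to 2.24%. At 5 d 7614 genes were called, 3624 higher and 3990 lower, and 1059 and 959 of them at least 2-fold.

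Between 16 h and 5 d the lipid synthesis genes climbed together. All 20 cholesterol genes rose (median 0.98, adjusted p = 2.82e-20), as did 13 of 14 fatty acid genes (median 1.04, adjusted p = 7.49e-14), and 21 of 27 replication genes rose with 1 fall (median 0.58, adjusted p = 1.67e-06). Hypoxia genes fell in 25 of 27 cases, 26 adjusted over the list alone (median -0.91, adjusted p = 4.65e-23), ribosomal protein genes in 43 of 43 (median -0.77, adjusted p = 1.14e-51) and mesenchymal genes in 11 of 16, 12 adjusted over the list alone (median -0.85, adjusted p = 9.25e-10). NF-kappaB and cytokine genes gave 15 falls and 1 rise of 22 (median -1.52, adjusted p = 3.27e-06), and steroid and related genes 9 falls of 12 (median -0.87, adjusted p = 7.16e-05, but adjusted p = 0.0655 with an estimated correlation). The mitosis list had 6 rises and 4 falls of 25 (median 0.09, adjusted p = 0.395). A further 6 lists passed camera with adjusted p from 7.3e-05 to 0.0384, but with adjusted p from 0.0883 to 0.525 with an estimated correlation. Their medians were -0.29 for the unfolded protein list, -0.23 for matrix genes, -0.21 for ERK feedback genes, -0.25 for autophagy genes, -1.02 for histones and 0.13 for mitochondrial transcripts. With quantile normalization the calls of the unfolded protein list (adjusted p = 0.136), matrix genes (adjusted p = 0.824) and ERK feedback genes (adjusted p = 0.28) were lost. The same normalization moved the median of ribosomal protein genes to -0.42 and that of mitochondrial transcripts to 0.54. Single genes that rose included KISS1 (3.88 ± 0.29), the organic anion transporter SLCO4C1 (3.67 ± 0.27), ALPP (3.11 ± 0.19) and the gluconeogenic enzyme FBP1 (2.49 ± 0.21), from low levels at 16 h. DCN (-6.95 ± 0.42) and LBP (-6.64 ± 0.40) fell, and GNLY, a cytolytic protein, was at least 30.0-fold lower. HSPA6, a heat shock protein whose close paralog makes its value uncertain, was at -6.43 ± 0.42. The test called 6665 genes, 3148 higher and 3517 lower.

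Of the genes called in both sphere comparisons, 2333 were higher at both times and 2264 lower at both, against 992 and 1058 for independent calls, and 608 went opposite ways. Both comparisons share the adherent libraries. Across 13789 genes the log2 fold changes had r = 0.730, though genes are not independent replicates, against 0.50 in 20 simulations of unchanged groups, with a covariance of 0.627 against 0.0319. The simulated genes varied independently of each other. Of the 1177 genes at least 2-fold higher at 16 h, 639 were at least 2-fold higher at 5 d and 666 were lower at 5 d than at 16 h.

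**Figure D2:**
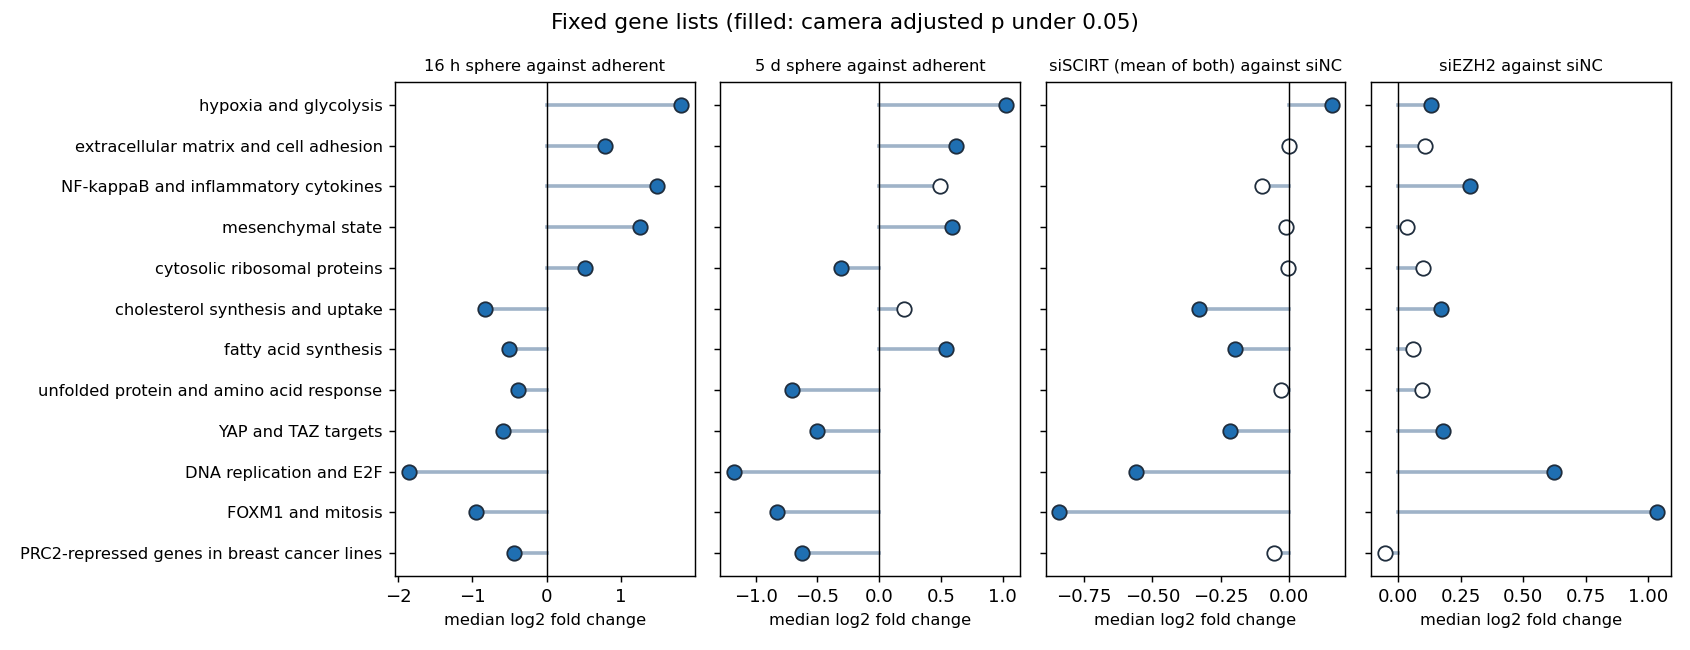
Median log2 fold change of the tested members of each gene list, by comparison, against adherent cells or siNC, with filled points for lists that passed camera. Replication genes stand at -1.86 at 16 h, -1.18 at 5 d and -0.56 for the mean of both siSCIRTs, and at 0.62 with siEZH2.

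With SCIRT silenced, cell cycle genes fell. NEK2, a mitotic centrosome kinase, fell from 1702 ± 263 normalized counts with siNC (SD, n = 3) to 683 ± 53.1 with siSCIRT 1 and 685 ± 74.6 with siSCIRT 2 (n = 3 each), a mean log2 fold change of -1.31 ± 0.10 (adjusted p = 2.6e-06). The spindle protein HMMR (-1.22 ± 0.13), the DNA glycosylase NEIL3 (-1.02 ± 0.12) and the amino acid transporter SLC6A14 (-1.53 ± 0.12) fell too. The cell cycle gene FAM72D was at -1.02 ± 0.15, a value made uncertain by its near-identical paralogs. Rises were led by the urea transporter SLC14A1 (1.33 ± 0.12), the granule protein SCG2 (1.28 ± 0.07), the adhesion molecule NEGR1 (1.23 ± 0.14), the water channel AQP5 (1.14 ± 0.16) and CHPF, a chondroitin synthesis factor (1.12 ± 0.13). ID3, an inhibitor of differentiation factors, rose by 1.10 ± 0.23, and the complement component C7 and the nuclear receptor NR4A3 by 0.95 ± 0.11 and 0.92 ± 0.13.

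Of 25 mitosis genes 24 fell with each siRNA, with medians of -0.91 for siSCIRT 1 and -0.77 for siSCIRT 2 (adjusted p = 3.16e-38 and 4.48e-34, but adjusted p = 0.091 and 0.151 with an estimated correlation). Examples for the mean of both were BUB1 (-0.97 ± 0.08), the spindle kinase AURKA (-0.92 ± 0.07) and the topoisomerase TOP2A (-0.85 ± 0.07), and CDC25B was at -0.02. Replication genes fell in 26 of 27 cases with each siRNA (medians -0.59 and -0.55, adjusted p = 1.89e-26 and 6.99e-25, but adjusted p = 0.107 and 0.151 with an estimated correlation), such as MCM10 (-0.86 ± 0.10) and MCM3 (-0.72 ± 0.07). Cholesterol genes fell in 15 and 13 of 20 cases, 18 each adjusted over the list alone (medians -0.35 and -0.32, adjusted p = 1.88e-16 and 1.92e-14, but adjusted p = 0.091 and 0.151 with an estimated correlation). Over both siRNAs HMGCS1 was at -0.64 ± 0.05. Fatty acid genes fell in 6 and 4 of 14 cases, 8 and 7 adjusted over the list alone (adjusted p = 2.27e-05 and 0.000873, but adjusted p = 0.091 and 0.166 with an estimated correlation). YAP and TAZ targets gave 7 falls and 1 rise of 19 with each, 8 falls and 2 rises adjusted over the list alone (adjusted p = 0.00165 and 0.01, but adjusted p = 0.091 and 0.151 with an estimated correlation), with CTGF at -0.75 ± 0.06 and CYR61 at -0.73 ± 0.06.

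With SCIRT silenced, hypoxia genes rose in 7 and 5 of 27 cases, 9 and 7 adjusted over the list alone (medians 0.18 and 0.14, adjusted p = 4.32e-05 and 0.00121, but adjusted p = 0.837 and 0.794 with an estimated correlation), the growth factor VEGFA by 0.40 ± 0.08 and the carbonic anhydrase CA9 by 0.52 ± 0.12. Histones, a sign of RNA quality, rose in 4 and 3 of 12 cases, 6 and 3 adjusted over the list alone (adjusted p = 0.000361 and 0.00634, but adjusted p = 0.239 and 0.463 with an estimated correlation). Mitochondrial transcripts fell in 1 and 2 of 13 cases, 2 and 8 adjusted over the list alone (medians -0.18 and -0.23, adjusted p = 0.00165 and 0.000663, but adjusted p = 0.58 and 0.481 with an estimated correlation). The other lists did not pass camera for the mean of both, though some members did. SOX2, a pluripotency factor in the stemness list, rose by 0.75 ± 0.15 and MYC fell by 0.25 ± 0.05. MUC1 rose by 0.78 ± 0.10, the adhesion linker TLN1 by 0.85 ± 0.08 and the collagen COL6A1 by 0.53 ± 0.05, while COL4A1 fell by 0.53 ± 0.06. IL6, an inflammatory cytokine (-0.52 ± 0.09), and PSAT1, an enzyme of serine synthesis (-0.80 ± 0.08), fell. Ribosomal protein genes gave 0 calls of 43 in limma (median 0.05 and -0.05). PRC2 subunits gave 1 rise and 3 falls of 10 for the mean, 3 and 4 adjusted over the list alone, with PHF1 at 0.49 ± 0.08. PRC2-repressed genes gave 4 rises and 1 fall of 19, 4 and 3 adjusted over the list alone (median -0.06, adjusted p = 0.953), with DKK1 at -0.47 ± 0.08.

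In limma 1693 of 16607 genes were called with siSCIRT 1 (769 higher, 924 lower), 1584 with siSCIRT 2 (746 and 838) and 2390 for their mean (1132 and 1258). With the replicate number as a block they were 3144, 3110 and 4030, and without the trend 964, 824 and 1531. Single libraries moved these counts by over 1.5 times as well. The siSCIRT 1 count was 887 without siNC replicate 3, 1069 without siNC replicate 1 and 945 and 976 without siSCIRT 1 replicates 2 and 3. The siSCIRT 2 count was 769 and 922 without siNC replicates 3 and 1 and 911 without siSCIRT 2 replicate 3, and the mean's 1242 and 1461 without siNC replicates 3 and 1. Both siRNAs called 563 genes higher and 664 lower, against 34.5 and 46.6 for independent calls, and 0 genes in opposite directions. The comparisons share the siNC libraries, which cannot be divided between them at n = 3, so shared controls enter the overlap. In 20 simulations of unchanged groups with shared controls r across genes was 0.497, against 0.773 observed. The simulated covariance was 0.0219, against 0.0719 observed. The simulated overlap was 0, but unchanged genes rarely pass the threshold, and the simulated genes varied independently of each other. The simulated overlap therefore cannot show how much of the observed overlap comes from shared controls. Between siSCIRT 1 and siSCIRT 2 limma called 0 genes, with 451 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 6. The 451 are under a share of 0.05 of the 16607 genes, so they are no hint of a difference. With the replicate number as a block limma called 7 genes between them. Camera still called 7 lists between them, with medians no larger than that of the mitosis list (-0.11, adjusted p = 6.8e-08, but adjusted p = 0.645 with an estimated correlation). With an estimated correlation camera called 0 lists between them, and so did the directional test of fry.

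With EZH2 silenced, cell cycle genes rose. CDC25C, a phosphatase that starts mitosis, went from 47.0 ± 14.6 normalized counts with siNC to 144 ± 13.6 with siEZH2 (SD, n = 2 each; log2 1.62 ± 0.22), and DTL, a replication-linked ubiquitin ligase subunit, rose by 1.51 ± 0.17. The chromosome motor KIF4A (1.43 ± 0.15) and the checkpoint kinase TTK (1.41 ± 0.17) rose too. MMP3, a matrix protease, rose from 29.4 ± 9.07 to 103 ± 5.32 (1.81 ± 0.25), and CSF2, a myeloid growth factor, from 387 ± 21.8 to 1077 ± 18.7 (1.47 ± 0.13). Falls included LIPA, the lysosomal acid lipase, from 3406 ± 306 to 1430 ± 109 (-1.25 ± 0.12), ALDH3A1, an aldehyde dehydrogenase (-1.31 ± 0.21), the complement protease C1S (-1.08 ± 0.14) and the nonmuscle myosin MYH10 (-1.09 ± 0.15).

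Of 25 mitosis genes 23 rose with siEZH2, 24 adjusted over the list alone, and 16 at least 2-fold (median 1.03, adjusted p = 1.96e-66, but adjusted p = 0.243 with an estimated correlation). The directional test of fry called 0 lists in this comparison, the mitosis list included. TPX2, a spindle assembly factor, rose by 1.23 ± 0.13 and AURKA by 1.18 ± 0.13, and CDC25B fell by 0.40. Replication genes rose in 19 of 27 cases, 25 adjusted over the list alone (median 0.62, adjusted p = 1.33e-31, but adjusted p = 0.243 with an estimated correlation), with MCM10 at 1.51 ± 0.21 and E2F1, which drives the list, at 1.05 ± 0.15. NF-kappaB and cytokine genes rose in 8 of 24 cases, 10 adjusted over the list alone (median 0.29, adjusted p = 7.6e-14, but adjusted p = 0.243 with an estimated correlation), among them the chemokine IL8 (1.21 ± 0.12), the prostaglandin synthase PTGS2 (0.93 ± 0.12) and the feedback inhibitor TNFAIP3 (0.91 ± 0.12). Hypoxia genes rose in 7 of 27 cases, 8 with 1 fall adjusted over the list alone (median 0.13, adjusted p = 0.00147, but adjusted p = 0.825 with an estimated correlation), the vasodilator peptide ADM by 0.92 ± 0.12. With quantile normalization the median of the hypoxia genes was 0.04. YAP and TAZ targets rose in 4 of 19, 6 adjusted over the list alone (median 0.18, adjusted p = 0.00341, but adjusted p = 0.425 with an estimated correlation), and cholesterol genes in 3 of 20, 4 adjusted over the list alone (median 0.17, adjusted p = 0.00341, but adjusted p = 0.825 with an estimated correlation). ERK feedback genes gave 4 rises and 1 fall of 27, 6 rises adjusted over the list alone (median 0.19, adjusted p = 0.0149, but adjusted p = 0.825 with an estimated correlation and 0.0782 with quantile normalization).

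The list of PRC2-repressed genes gave 1 rise and 1 fall of 19 with siEZH2, 1 and 2 adjusted over the list alone (median -0.05, adjusted p = 0.684). The riser was DKK1 (0.74 ± 0.12), and TIMP2 fell by 0.98 ± 0.12. PRC2 subunits gave 1 rise of 10, JARID2 (0.36 ± 0.12). Stemness markers gave 4 rises and 1 fall of 14, 6 and 3 adjusted over the list alone (adjusted p = 0.0872), with MYC at 0.56 ± 0.12 and the receptor NOTCH3 at -0.73 ± 0.19. For p53 targets (17), autophagy genes (23) and mitochondrial transcripts (13) limma called 0 members, and the remaining lists did not pass camera. In all 1082 of 15823 genes were called, 617 higher and 465 lower. DESeq2 called 675, limma without the trend called 0 and with the replicate number as a block 532, and limma called 342 without siNC replicate 1 and 508 without siNC replicate 2.

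**Figure D3:**
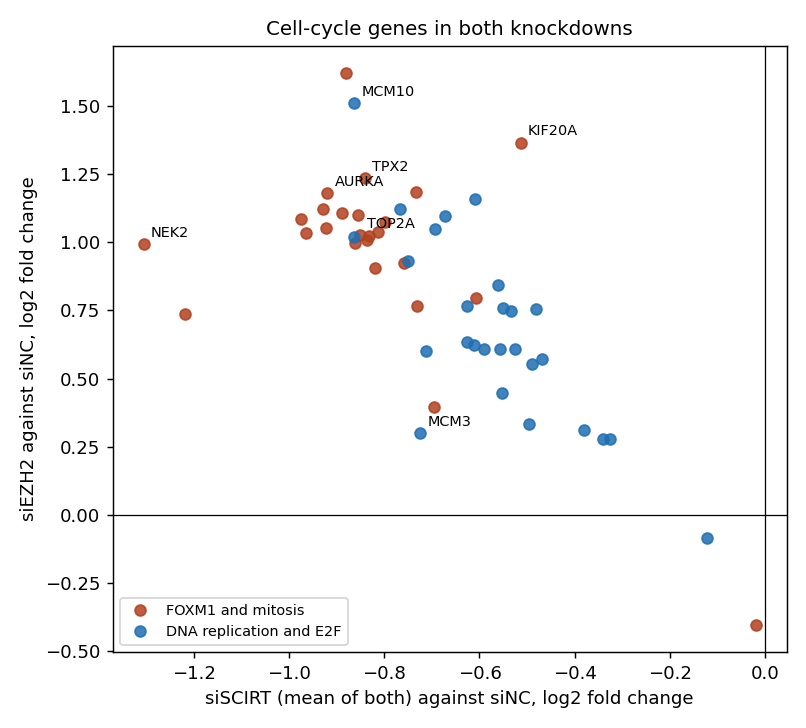
Log2 fold change of each mitosis and replication gene with siSCIRT (mean of both) against that with siEZH2, points being genes. Of the mitosis genes 24 were called below 0 with siSCIRT and 23 above 0 with siEZH2.

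Among the gene lists, the knockdown responses differed by the largest median in the mitosis genes. In a fit over the 13 siRNA libraries the siEZH2 response minus the siSCIRT response had a median of 1.88 over the mitosis genes, 24 of them higher and 1 lower (adjusted p = 1.02e-41, but adjusted p = 0.0516 with an estimated correlation), for example TPX2 at 2.07 and BUB1 at 2.06. Replication genes differed by 1.24, all 26 called being higher (adjusted p = 3.32e-32, but adjusted p = 0.0516 with an estimated correlation). Of the genes called higher with siEZH2, 614 were tested in the siSCIRT mean, where 279 were lower and 19 higher (median -0.21, adjusted p = 2.66e-27). Of those called lower with siEZH2, 456 were tested and 84 were higher and 19 lower (median 0.09, adjusted p = 0.000298). Across 15369 genes, which are not independent replicates, the responses had r = -0.27 (Spearman -0.23). Genes called lower in 5 d spheres had a median of -0.04 with siSCIRT (adjusted p = 0.000346, but adjusted p = 0.376 with an estimated correlation) and of 0.09 with siEZH2 (adjusted p = 6.03e-09, but adjusted p = 0.0983 with an estimated correlation). Genes called higher in 5 d spheres had medians of 0.02 and -0.02 (adjusted p = 0.104 and 0.0559).

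**Figure D4:**
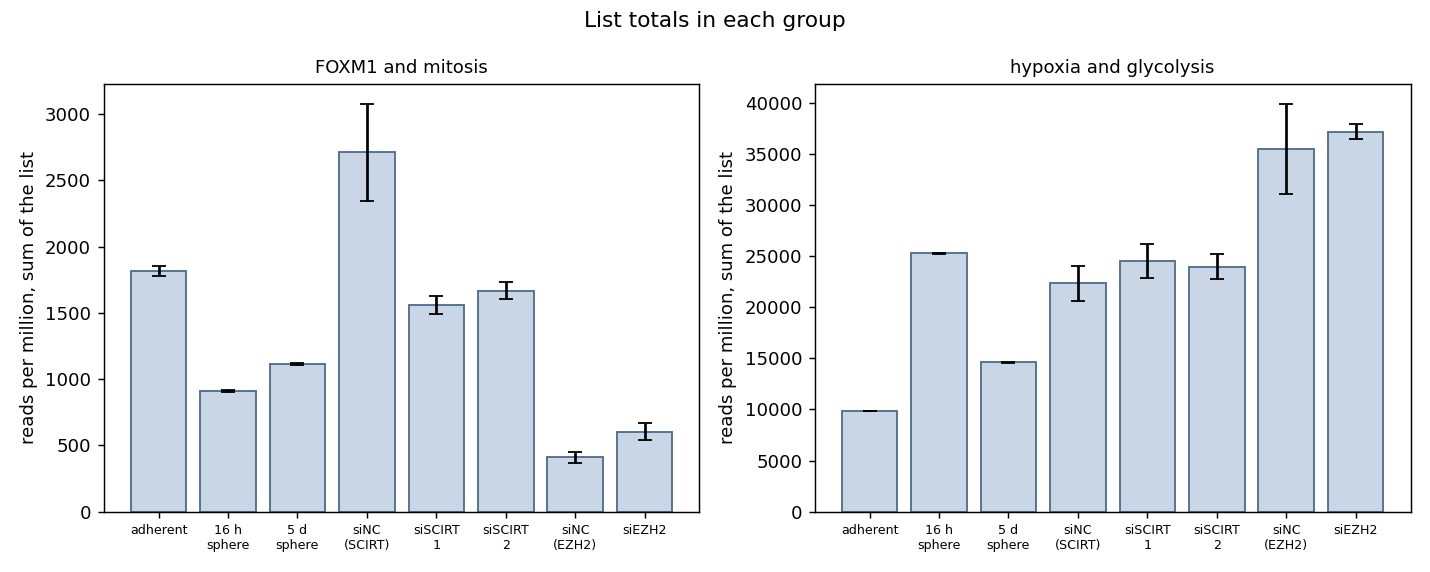
Reads of the mitosis and of the hypoxia list, summed and scaled to library totals (CPM), with bars for group means and error bars for the SD between libraries. Mitosis genes stand at 2709 CPM with siNC of the siSCIRT table and at 413 CPM with siNC of the siEZH2 table.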

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

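The tests of the difference between the siRNA responses, of the starting level, of scaling between libraries and of abundant genes were chosen after the results were seen.

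Mitosis genes fell with siSCIRT and rose with siEZH2, and a fit over both siRNA tables found that the responses differed by a median log2 difference of 1.88 (adjusted p = 1.02e-41, but adjusted p = 0.0516 with an estimated correlation). Scaling between libraries as the whole cause is argued against, since a factor common to a library moves all genes alike, while the list stood apart from the median of all genes (0.00903 with siEZH2 and 0.00792 for the mean of both siSCIRTs). With quantile normalization, TMM and DESeq2 size factors the list's median was at least 1.03 with siEZH2 and between -0.85 and -0.84 for that mean. The DESeq2 size factors nearly repeat the authors' own scaling, so only quantile normalization and TMM are separate checks. A different starting level remains a candidate explanation, because 24 of the 25 mitosis genes stood in the siEZH2 table's controls at under 50% of the level in the siSCIRT table's controls, with a median ratio of 0.114. Each siRNA was compared with controls of its own table, and these control sets differed in more than mitosis genes. Hypoxia genes summed to 35483 ± 4381 CPM in the siEZH2 table's controls (SD, n = 2). In the siSCIRT table's controls they summed to 22330 ± 1726 CPM (n = 3). EZH2 stood at 15.6 and 47.6 CPM, while steroid and related genes were alike (534 and 549 CPM). An effect of the gene silenced and any difference between the control sets may thus both have entered the difference. How fast the control cells were cycling was not measured. A difference between SCIRT and EZH2 in what their loss does to cycling cells stays open as the biological explanation, and it was not tested apart from the tables.

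Ribosomal protein genes were above adherent cells at 16 h and below them at 5 d (at 5 d adjusted p = 5.19e-13, but adjusted p = 0.058 with an estimated correlation), and the test between the time points gave a median log2 fold change of -0.77 (adjusted p = 1.14e-51). With quantile normalization the median between the time points was -0.42. A few abundant genes taking part of the reads are argued against as the whole cause: the 100 most abundant other genes took a larger share of reads in spheres (27.1% at 16 h and 24.1% to 24.3% at 5 d, against 20.7%), which lowers other genes at both times, and with them left out of the totals the ribosomal protein genes were still at 1.30 times the adherent share at 16 h and at 0.84 times at 5 d. For the fall at 5 d, scaling between libraries is argued against too, since with quantile normalization, which moved the list at 16 h, the median was -0.39 (adjusted p = 2e-16). That lies beyond the SD of 0.289, which is a spread between the genes and not an error of the median. With TMM the median was -0.29. DESeq2 size factors hardly moved the list either, but they nearly repeat the authors' own scaling and are no separate check. For the rise at 16 h, scaling and a real rise cannot be told apart, because the median was 0.51 with TMM and with DESeq2 size factors but 0.059 with quantile normalization, within the SD of the genes of 0.157. A change of translation capacity between the culture times stays open as the biological explanation and was not tested.

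Fatty acid synthesis genes differed between the time points, with a median log2 fold change of 1.04 from 16 h to 5 d after a fall at 16 h and a rise at 5 d against adherent cells (adjusted p = 0.051 and 0.058 with an estimated correlation). Replication and E2F genes differed between the siRNA responses by a median of 1.24 (adjusted p = 3.32e-32, but adjusted p = 0.0516 with an estimated correlation). Cholesterol genes differed between the siRNA responses by 0.49 (adjusted p = 4.83e-11, but adjusted p = 0.172 with an estimated correlation). YAP and TAZ targets differed between the siRNA responses by 0.35 (adjusted p = 0.000315, but adjusted p = 0.0516 with an estimated correlation).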

How the results depend on the processing

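The deposited transformed values and the counts of genes changed at least 2-fold were chosen after the data were seen. The named-gene results were picked from these data as passing the main test, many without overlap between groups, which favored a high share kept. For the 448 named-gene results, 6252 of 6561 alternative values kept their direction and side of the threshold, 303 no longer passed it (159 of them with a library left out, and most of the rest without the trend) and 6 reversed. All 6 came with quantile normalization: at 16 h CD44 went to -0.038, MT-CO2 to -0.47, MT-ND4 to -0.54, MT-ATP6 to -0.45 and MT-ND5 to -0.46, and at 5 d MT-CO2 went to 0. Culture counts (16 h, 5 d, 5 d against 16 h) moved by over 1.5 times at 2-fold with a mean of at least 50 (1571, 1305 and 781), where fewer genes were tested, and in no other alternative. If the libraries of a culture pair were repeats of 1 culture, each group would hold 1 sample and no test could be had. Without the trend limma called 964, 824 and 1531 genes for siSCIRT 1, siSCIRT 2 and their mean and 0 for siEZH2, which had 675 with DESeq2. With the replicate number as a block the counts were 3144, 3110 and 4030, with 7 between the siSCIRTs and 532 for siEZH2, and 7521, 7687 and 6771 in culture. Numbers paired the siSCIRT libraries in part (11 of 18 best partners had the same number, correlations -0.00432 to 0.575), but not the culture (-0.0198 to -0.00379) or siEZH2 libraries (-0.0140). Between siSCIRT 1 and siSCIRT 2 limma called 2 genes with no filter and 1 with only the 2 groups, and DESeq2 6. With a library left out the counts ran from 6006 to 6590, 6153 to 7047 and 5570 to 6177 in culture, 887 to 1829 for siSCIRT 1, 769 to 1815 for siSCIRT 2, 1242 to 2582 for their mean, 0 to 0 between them and 342 to 1040 for siEZH2. In groups of 2 this leaves a lone library, which is assumed to vary like the others. The libraries that moved a count by over 1.5 times were siNC replicates 1 and 3 (siSCIRT 1 1069 and 887, siSCIRT 2 922 and 769, mean 1461 and 1242), siSCIRT 1 replicates 2 and 3 (945 and 976), siSCIRT 2 replicate 3 (911) and siNC replicates 1 and 2 of the siEZH2 table (342 and 508). With an estimated correlation 9, 4 and 7 lists were called in culture, against 17, 15 and 14, and 0 in each siRNA comparison, against 8, 8, 8, 7 and 7. Quantile normalization ended the list calls of ribosomal proteins (adjusted p = 0.0536), PRC2-repressed (0.0672) and ERK genes (0.145) at 16 h, mesenchymal genes (0.0638) and mitochondrial transcripts (0.0975) at 5 d, unfolded protein (0.136), matrix (0.824) and ERK genes (0.28) from 16 h to 5 d, fatty acid genes between the siSCIRTs (0.0598) and ERK genes with siEZH2 (0.0782). It brought others past the threshold (autophagy at 16 h, adjusted p = 0.0482, epithelial and NOTCH and WNT genes from 16 h to 5 d, 0.0296 and 0.045, and epithelial and luminal genes with siEZH2, 0.0442 and 0.0424). The directional test of fry called 0 lists between the siSCIRTs and for siEZH2. At an adjusted p under 0.01 both siRNAs shared 572 calls, against 1227, since the threshold is stricter. With the 200 largest changes the genes lower with siEZH2 (median 0.089 with siSCIRT) and those lower in 5 d spheres (0.029 with siEZH2) no longer passed, and those higher in 5 d spheres did (0.12 with siSCIRT, -0.14 with siEZH2, the latter with adjusted p = 0.125 with an estimated correlation). Apart from fewer genes tested and the stricter threshold, the cause was not tested. The scalings moved the median of all genes by at most 0.033. Depth limits the culture libraries first, whose totals start at 6104222 reads, so that genes at 0 to 3 reads in a group have lower bounds or wide intervals.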

Other observations

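In 5 d spheres the growth inhibitor CDKN1A rose by 1.13 ± 0.05 on the log2 scale, while the stress cytokine GDF15 (-2.51 ± 0.10) and the apoptosis gene BAX (-1.01 ± 0.10) fell. All are p53 targets, of which 4 rose and 4 fell of 16 (adjusted p = 0.947). Interferon-stimulated genes gave 10 rises and 5 falls of 27 at 5 d (adjusted p = 0.236), with the antiviral synthetase OAS2 at 1.23 ± 0.10 and SAMD9 at 1.23 ± 0.12. Epithelial genes gave 7 rises and 5 falls of 14 (adjusted p = 0.125), among them MUC1 (2.38 ± 0.16) and the tight junction protein CLDN7 (1.16 ± 0.12). Stemness markers gave 3 rises and 4 falls of 11 (adjusted p = 0.879), the integrin ITGA6 being at 1.19 ± 0.04 and the Polycomb protein BMI1 at -0.97 ± 0.10. LGR5, at 1 read in 5 d spheres, was 80.6 times higher in adherent cells (14.5 to 3182). NF-kappaB and cytokine genes gave 10 rises and 7 falls of 22 (adjusted p = 0.125), with CSF3 at 5.24 ± 0.32 and the cytokine IL11 at -2.75 ± 0.25.

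With siEZH2, 4 of 33 interferon-stimulated genes rose, or 6 with 3 falls adjusted over the list alone (adjusted p = 0.48), including IFIT1 (0.73 ± 0.13), OASL (0.57 ± 0.14) and the ubiquitin-like ISG15 (0.46 ± 0.12). Matrix genes gave 3 rises of 31, or 5 with 2 falls adjusted over the list alone (adjusted p = 0.0606), namely COL4A1 (0.64 ± 0.12), the collagen COL4A2 (0.52 ± 0.12) and the glycoprotein TNC (0.58 ± 0.12). The amino acid genes PSAT1 (0.63 ± 0.13), SESN2 (0.58 ± 0.13) and SLC7A5 (0.47 ± 0.12) were the 3 risers among 21 of their list (adjusted p = 0.0648). Among luminal markers the secreted TFF3 (-0.50 ± 0.14) and the transcription factor SPDEF (-0.38 ± 0.12) fell, 2 of 12 (adjusted p = 0.0805). For the mean of both siSCIRTs 5 of 23 autophagy and lysosome genes rose (adjusted p = 0.423; 4 were called with siSCIRT 1 and 3 with siSCIRT 2), among them the kinase ULK1 (0.31 ± 0.07), the transcription factor TFEB (0.47 ± 0.11) and the protease CTSD (0.31 ± 0.07). For the same mean, among ERK-responsive genes, the EGF receptor ligand HBEGF (-0.45 ± 0.07) and the cyclin CCND1 (-0.36 ± 0.06) fell, in a list of 27 with 2 rises and 4 falls (adjusted p = 0.88). CCND1 rose with siEZH2 by 0.43 ± 0.13, and the ERK inhibitor SPRY2 by 0.69 ± 0.12.

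The tests of this part, on the medium and on other splits of the libraries, were chosen before the values they measure were seen. Glucocorticoid-responsive genes were higher in spheres than in adherent cells, FKBP5 being at 26.8 times the adherent level of reads at 16 h and at 26.1 times at 5 d. A candidate explanation is the B27 medium of the spheres, rather than the time in suspension. It would place the 48 h control spheres of both siRNA tables, kept in the same medium, at least 2-fold above adherent cells in at least 5 of the 6 genes. Of them 2 were so in both tables, TSC22D3 (2.48 and 3.72 times) and PER1 (4.49 and 5.94 times). FKBP5 was over 2-fold in the siSCIRT table's controls and at 1.30 times in the siEZH2 table's, DUSP1 was under 2-fold in both, KLF9 was at 0.973 and 1.33 times, and ZBTB16 was not listed in the siRNA tables. The prediction was thus not met. Every gene listed stood lower in both sets of control spheres than in 16 h and 5 d spheres, PER1 being at 15.2 and 8.06 times in the latter. The control spheres had been in suspension in the sphere medium for 48 h. Their values argue against the medium alone, or the time in suspension alone, as enough for the whole rise. A part played by either stays open, and the 2 cannot be told apart by this test. The control spheres differ from the other spheres by transfection and table as well.

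Other splits of the same libraries were tested for the siSCIRT counts. For siSCIRT 1 against siNC the real split called 1693 genes and the highest other 1, so that 1 of 10 splits called as many, and 10 splits are too few for a share under 0.05. For siSCIRT 2 the real split called 1584 and the highest other 0, again 1 of 10 and too few. Between siSCIRT 1 and siSCIRT 2 the real split and the highest other both called 0 in limma, with 451 genes of the real split at an unadjusted p under 0.05, fewer than chance alone would give. Any split reaches a count of 0, so the outcome of 10 in 10 splits was fixed beforehand and says nothing about chance. For the mean of both siRNAs 3 of 100 splits called as many genes, with 2390 for the real split and 2866 for the highest other. These 3 splits kept the siNC libraries together as the controls, and the highest of the other 97 called 477. Only draws of that control set reached the count, so the share of 3 in 100 is how often it was drawn. By that share chance is unlikely but not excluded. The splits also treat the libraries as interchangeable, though replicate numbers paired them in part.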
